A study of Mus musculus with 7 samples.

How the data were processed

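RNA was sequenced from splenocytes of C57Bl/6 mice after magnetic removal of cells carrying CD43, a surface protein of T cells, myeloid cells and some B cells, which leaves mostly resting B cells. Per the labels, 4 libraries came from mice with a conditional knockout (cKO) of Foxp1 made with a Cre active in B cells, and 3 from wild type mice. Groups and replicate numbers were taken from the sample titles. The labels do not say that the libraries come from separate animals, so p-values measure the spread between these samples, which may be technical. The description labels name the sequencing lane: wild type 2 and 3 and cKO 1 and 4 ran on lane 5, and wild type 1 and cKO 2 and 3 on lane 7.

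The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each gene and library, with a status for each value, per the file headers. The submitters' processing notes name TopHat2, Cufflinks and Cuffdiff without versions or roles. They name the mm9 build, but the positions in the deposited tables overlapped the GRCm38 gene for 99.4% of 21320 symbols matched once, so positions are given as in the tables, in GRCm38 coordinates. The design fixed before the data were examined spoke of RPKM. The values proved to be FPKM, and the same test was used. A second table deposited by the authors holds Cuffdiff's comparison of arms named q1 and q2, with a test statistic (a signed score), a p-value and a q-value per gene, per the file headers. No header or label says which arm is which genotype, so the level of each arm was not used, and the sign of the test statistic gave the direction of q2 over q1.

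FPKM keep depth only indirectly. In single-transcript genes of at least 1500 bases, the most frequent value of FPKM times length in kilobases was taken within a preset window of low values. It approximates the weight of 1 fragment. This value was 0.0257 in cKO 4 and 0.0157 to 0.0219 in the other libraries, so cKO 4 appeared the shallowest. This rests on GENCODE M21 transcript lengths. Counting error could therefore not be given per gene, and errors are SDs over libraries. FPKM of a gene also depends on what other transcripts take. Small RNA genes held between 11.7% and 59.0% of the summed FPKM of a library. FPKM divide by transcript length, so for such short genes this is not their share of the fragments.

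Of 23845 rows, 23508 had the status OK in every library and entered the tests. The rest were 324 rows with a LOWDATA status and 13 with a HIDATA or FAIL status, for which the value is no full estimate. Spreadsheet software had turned 27 symbols into day numbers, and these rows are not named. Genes with a mean FPKM of at least 1 over the 7 libraries, 10065 in all, were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 0.5), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale, which understates the change of low genes. No covariate was in the fit. A fit with the lane as a term was planned as an alternative, and its values are given beside the others because 6733 genes differed between lanes in it.

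Before the data were examined, 33 gene lists were fixed (B cell stages and functions, cell processes, and markers of other cell types that a spleen preparation can hold). Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, which compares members with all other genes tested, and again with an estimated correlation and with fry. The 13 immunoglobulin constant genes had no tested member, so 32 lists were tested. A list score is the mean of log2(FPKM + 0.5) over the members. The genes named were Foxp1, then up to 10 higher and 10 lower genes with the largest fold among those past the threshold whose groups did not overlap (antigen receptor segments, predicted genes and small RNA genes left out), then up to 4 members with the smallest p of each list past the threshold, members past the threshold over all genes, and the 2 most abundant members of each list of another cell type. Genes named outside this rule are said to be. A few genes that the rule takes in are not reported here.

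On simulated values for the 10065 genes of the comparison of cKO with wild type, built with the lane effects and residual spread of the real genes, the fit without a lane term recovered 3% of 100 genes changed by 1 on the log2 scale and 69% of 100 changed by 2, with 0 unchanged genes called. The fit with the lane term recovered 70% and 96%, with 8 unchanged genes called. The noise was drawn for each gene on its own, and the lane effects were those the fit assumes. The simulation therefore does not show how many false calls genes that vary together would give. Alternatives covered the pseudocount, the filter on low values, the limma settings, scaling, the lane, each library left out, repeated symbols and the threshold. Figures were drawn with matplotlib 3.10.9.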

Results

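Gene expression was measured by RNA sequencing in CD43-depleted splenocytes from 4 libraries with a B cell knockout of Foxp1 (cKO) and 3 wild type libraries. Foxp1 encodes a forkhead transcription factor of lymphocytes. The design asks how the B cell transcriptome differs without it. FPKM at or above 1 was reached by 9488 to 9738 rows in the wild type libraries and by 9598 to 10419 in the cKO libraries. The first principal component held 61.7% of the variance and set lane 7 apart from lane 5, and the second held 21.6% and set the genotypes apart. The labels do not say whether the lanes also differ in preparation. In lane 7 the erythroid list score was 5.53 (wild type 1), 6.41 (cKO 2) and 7.21 (cKO 3). In lane 5 it was 3.37 (wild type 2), 2.12 (wild type 3), 6.08 (cKO 1) and 2.79 (cKO 4). Lane may therefore stand for preparation or cell makeup as well as sequencing. Small RNA genes, among them Rmrp, held 11.7% of the summed FPKM in cKO 4 and 40.0% to 59.0% in the other 6 libraries, which is not a share of fragments.

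**Figure D1:**
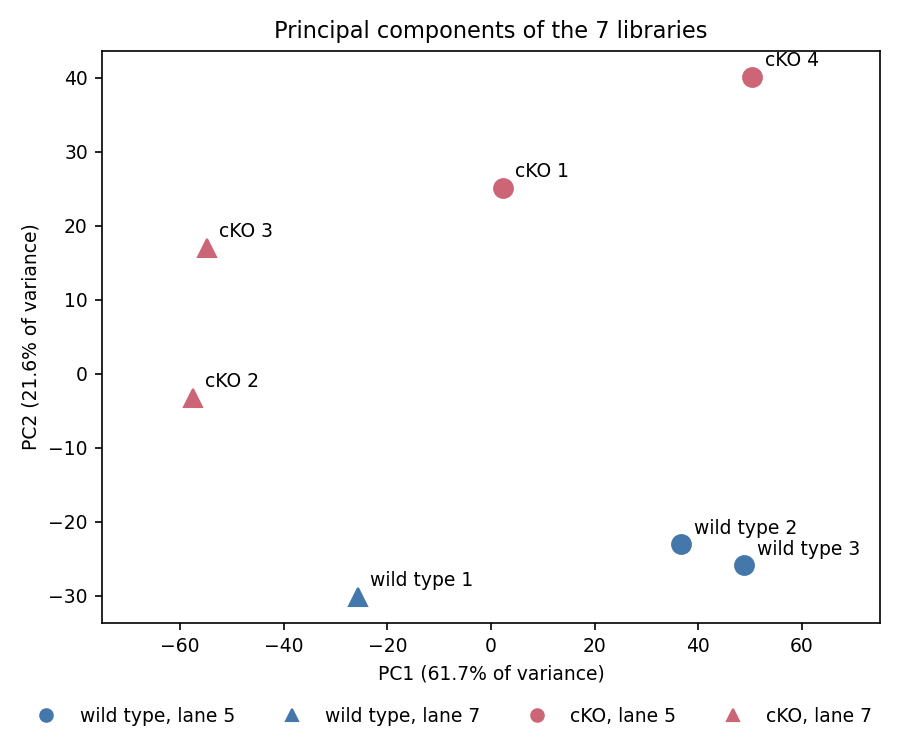
Principal components of log2(FPKM + 0.5) for the 7 libraries, with PC1 (61.7% of variance) on the x axis and PC2 (21.6%) on the y axis, colour for genotype and symbol for lane. All 3 lane 7 libraries lie below 0 on PC1 and all 4 lane 5 libraries above 0, and each cKO library lies above each wild type library on PC2.

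Foxp1 (chromosome 6, 98925342 to 99435345) was lower in each cKO library than in each wild type library, at 38.1 ± 4.66 FPKM in wild type (SD, n = 3) and 21.9 ± 4.90 in cKO (SD, n = 4). Its log2 fold change was -0.81 (SE 0.22), short of the threshold in limma's moderated test over all genes (adjusted p = 0.159), and -0.75 with the lane as a term (adjusted p = 0.0104). Within lanes, Foxp1 differed by -0.69 in lane 5 and -0.83 in lane 7. A two-sided exact permutation test gave p = 0.0571, the smallest that the 35 splits of 4 and 3 libraries allow. FPKM of a whole gene includes exons outside the deleted part, so the Foxp1 level checks the labels only in part.

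**Figure D2:**
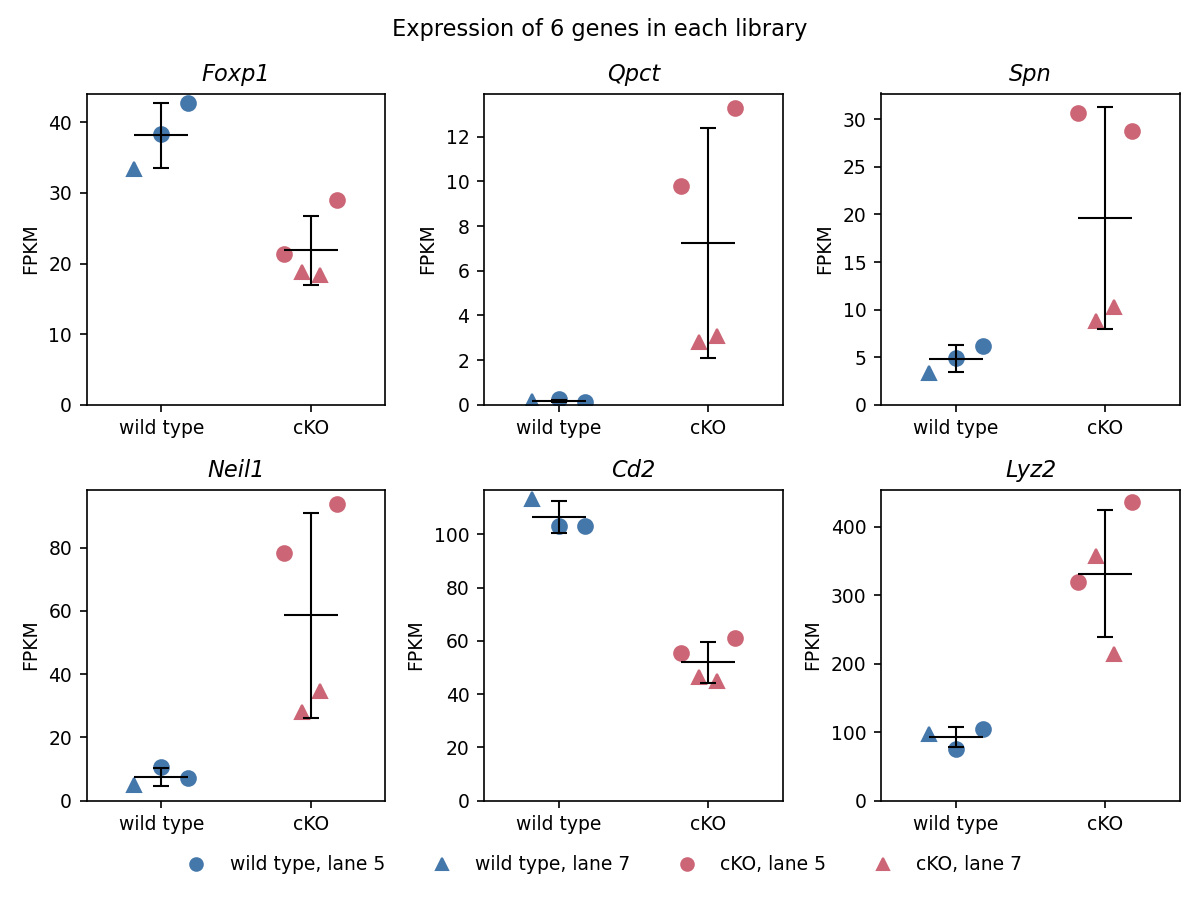
FPKM of 6 genes in each library, with wild type and cKO on the x axis and FPKM on the y axis from 0. Points are libraries with a symbol for the lane, and bars are the mean ± SD (n = 3 wild type, n = 4 cKO). For each of Foxp1, Qpct, Spn, Neil1, Cd2 and Lyz2 the values of the groups do not overlap.

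Against wild type, the cKO libraries had higher expression of 128 genes and lower expression of 5. The labels name no control that carries the Cre, so effects of the Cre cannot be told apart from loss of Foxp1. The largest increases were those of Qpct, a glutaminyl cyclase, with a log2 fold change of 3.28 (SE 0.51), Lipc, hepatic lipase, with 2.98 (SE 0.44), and Plb1, a phospholipase, with 2.83 (SE 0.46). The DNA glycosylase gene Neil1 rose from 7.48 ± 2.84 FPKM (SD, n = 3) to 58.7 ± 32.4 (SD, n = 4), and the protease inhibitor gene Slpi from 9.51 ± 4.70 to 60.1 ± 13.6. Chi3l3, Fpr1, Tnfrsf21, Csf1r and Emilin2 rose by 2.22, 2.12, 2.08, 2.06 and 1.99 on the log2 scale. Csf1r is the receptor of a macrophage growth factor and Fpr1 a chemotactic receptor of phagocytes. Reads of Chi3l3 may be shared with near-identical paralogs, so its value is uncertain.

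Crisp3 fell the most, from 3.99 ± 1.09 FPKM in wild type (SD, n = 3) to 0.605 ± 0.198 in cKO (SD, n = 4), with a log2 fold change of -2.01 (SE 0.27). Cyp4f18, a cytochrome P450, fell from 42.2 ± 9.29 to 16.1 ± 4.31 FPKM, and Cd2, an adhesion receptor of lymphocytes, from 106.5 ± 5.92 to 52.0 ± 7.62. Scn4a and Fkbp11 fell by 1.32 and 1.27 on the log2 scale. Adjusted p-values of the 133 genes lay between 0.0447 and 0.0495 in limma's moderated test, and all 133 had groups that did not overlap. Over all genes tested 10.1% had such groups, against 5.71% by chance. At an unadjusted p under 0.05, 962 genes were higher and 111 lower, where 503 in all were expected with no effect.

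With the lane as a term limma called 965 genes higher and 120 lower, which included all 133. This term may take out differences in preparation or cell makeup along with those of sequencing. Lane 5 alone gave 587 higher and 25 lower, and lane 7 alone 247 and 36. In lane 7 the spread came from the 2 cKO libraries and limma's pooling over genes, and the 1 wild type library was assumed to vary like them, so these counts carry little weight. The count of 133 depended on single libraries: limma called 0 genes without wild type 3 or without any one of the cKO libraries, with 608 to 1967 genes at an unadjusted p under 0.05, 1 gene without wild type 2, and 220 without wild type 1. Centring each library on its median gave 233 higher and 71 lower genes, quantile normalization 137 and 29, and both together with the lane term gave more lower than higher genes (952 and 1276 with centring, 814 and 1168 with quantile normalization).

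Markers of cells other than B cells were higher in the cKO libraries. Of 90 tested members of the 8 marker lists, 86 had a positive fold change and 9 rose past the threshold, a share of 10% against 1.19% of other genes. Members of a list varied together, with estimated correlations of 0.0942 to 0.977 over the 8 lists, and the smallest limma camera adjusted p of a marker list with an estimated correlation was 0.105. In the monocyte, macrophage and dendritic list 6 of 24 members rose (23 adjusted over the list alone), with a median log2 fold change of 1.79. Lyz2, the lysozyme of macrophages, rose from 92.7 ± 14.9 FPKM (SD, n = 3) to 331.5 ± 92.3 (SD, n = 4), Tyrobp, a signalling adaptor of myeloid and NK cells, from 103 ± 25.0 to 265.7 ± 16.8, Fcer1g from 17.1 ± 5.14 to 67.4 ± 10.1 and Cd68 from 5.83 ± 1.95 to 19.9 ± 4.52. In the neutrophil list 2 of 9 rose (9 adjusted over the list alone): S100a8 by 1.87 and Mpo, myeloperoxidase, by 1.75 on the log2 scale. S100a9 and Camp had log2 fold changes of 1.73 and 1.93 (limma adjusted p = 0.0529 for each). In the NK cell list 1 of 10 rose (5 adjusted over the list alone), the granzyme gene Gzma, from 6.38 ± 0.604 to 22.0 ± 4.59 FPKM, while Klrd1 had a log2 fold change of 1.56 (limma adjusted p = 0.0607).

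None of the members of the other marker lists passed the threshold over all genes. Adjusted over the list alone, 5 of 8 platelet and megakaryocyte genes were higher, with Itga2b at 1.15 and Tubb1 at 1.52 on the log2 scale, 3 of 5 stromal and endothelial genes, with Stab2 at 1.36, and 0 of 11 erythroid and 0 of 14 T cell genes in limma, with 1 of each list at an unadjusted p under 0.05. By limma's camera 7 of the 8 marker lists rose against all other genes. The adjusted p was 1.81e-26 for monocytes, macrophages and dendritic cells (adjusted p = 0.105 with an estimated correlation), 2.48e-12 for neutrophils (adjusted p = 0.225 with an estimated correlation), 1.44e-08 for NK cells (adjusted p = 0.501 with an estimated correlation) and 4.57e-06 for platelets (adjusted p = 0.501 with an estimated correlation). It was 0.000123 for erythroid markers (adjusted p = 0.644 with an estimated correlation), 0.00258 for T cells (adjusted p = 0.758 with an estimated correlation) and 0.00263 for stromal cells (adjusted p = 0.385 with an estimated correlation). The T cell call was lost without wild type 1 (limma camera adjusted p = 0.0649). The plasmacytoid dendritic list did not pass (limma camera adjusted p = 0.112); its most abundant member, Ly6d, which B cells also express, stood at 907 ± 49.0 FPKM in wild type (SD, n = 3) and 485.2 ± 32.8 in cKO (SD, n = 4). Spn, which encodes the depleted surface protein CD43, stood at 4.83 ± 1.41 and 19.6 ± 11.7 FPKM, with a log2 fold change of 1.74 (limma adjusted p = 0.148), and 1.94 with the lane term (limma adjusted p = 0.000603). With the lane term, 66 of the 90 markers were called higher by limma.

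**Figure D3:**
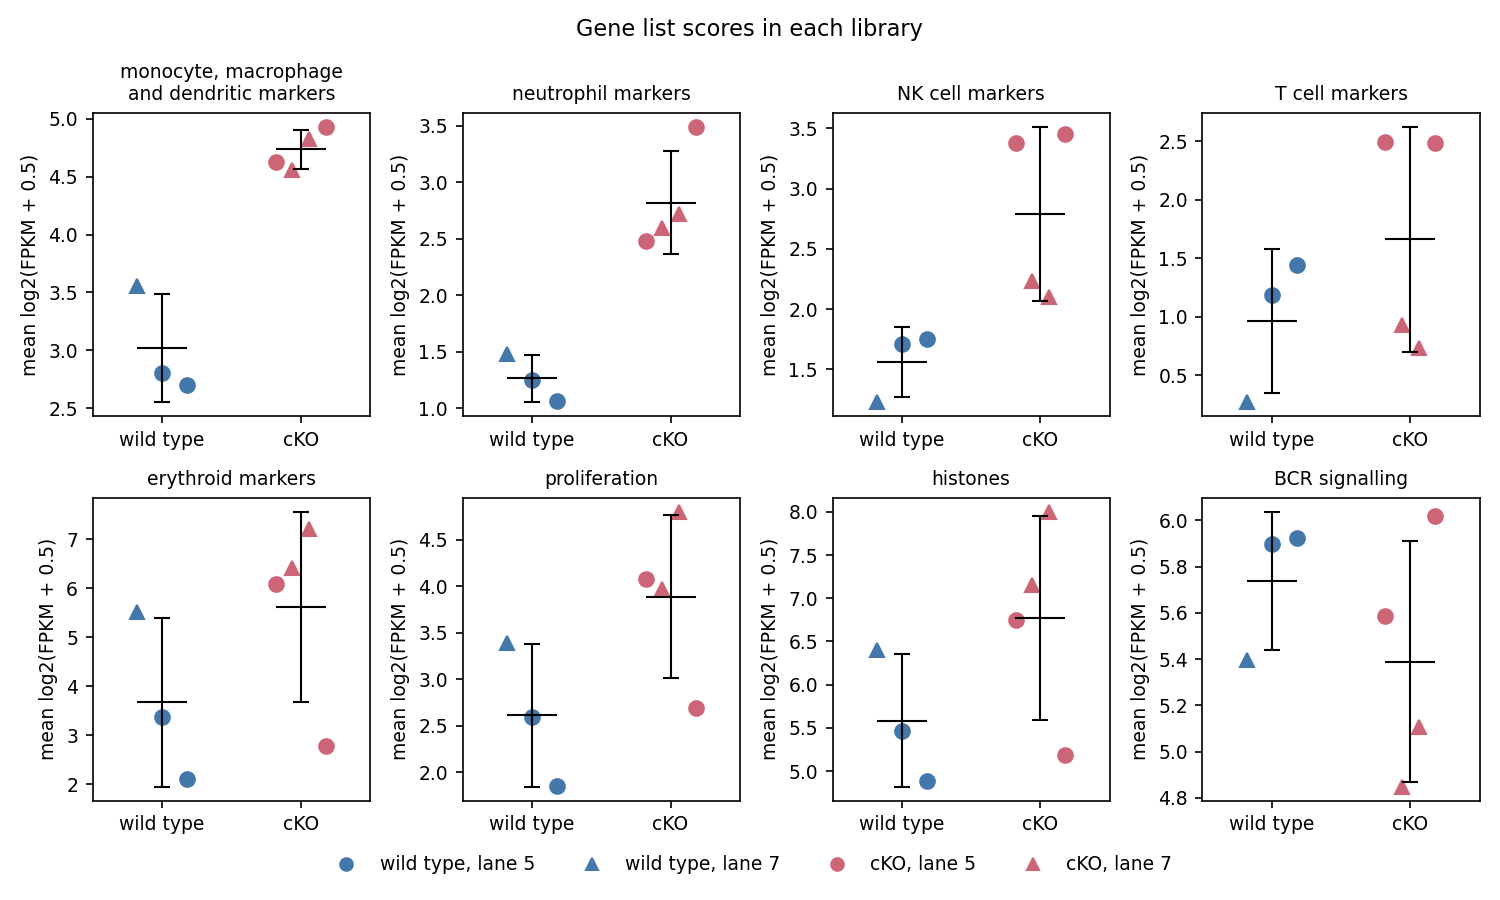
Scores of 8 gene lists in each library, with genotype on the x axis and the mean of log2(FPKM + 0.5) over the members on the y axis, which does not start at 0. Points are libraries with a symbol for the lane, and bars are the mean ± SD (n = 3 wild type, n = 4 cKO). The monocyte, macrophage and dendritic score lies at 4.56 to 4.93 in cKO and 2.70 to 3.55 in wild type, while the erythroid, proliferation and histone scores of cKO 4 lie among those of wild type.

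Cell cycle and histone genes rose as lists. All 25 proliferation genes had a positive fold change, with a median of 1.37 on the log2 scale (limma camera adjusted p = 5.67e-12, adjusted p = 0.501 with an estimated correlation), and 0 passed limma's threshold over all genes or adjusted over the list alone, with 12 at an unadjusted p under 0.05 and 8 called with the lane term. Top2a, a topoisomerase of dividing cells, stood at 13.0 ± 9.10 FPKM in wild type (SD, n = 3) and 38.9 ± 20.3 in cKO (SD, n = 4), and the mitotic kinase gene Aurkb at 4.58 ± 1.80 and 11.4 ± 5.13. Of 68 histone genes 62 had a positive fold change, with a median of 1.23 (limma camera adjusted p = 1.60e-13, adjusted p = 0.644 with an estimated correlation), and 0 passed limma's threshold over all genes or adjusted over the list alone, with 14 at an unadjusted p under 0.05. The erythroid score moved with both lists: it was 5.53, 3.37 and 2.12 in wild type 1 to 3 and 6.08, 6.41, 7.21 and 2.79 in cKO 1 to 4. Klf1, a transcription factor of red cell precursors, ranged widely, at 6.45 ± 7.26 FPKM in wild type (SD, n = 3) and 40.4 ± 30.9 in cKO (SD, n = 4).

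Interferon response genes rose as a list too, with a median log2 fold change of 0.39 over 23 members (limma camera adjusted p = 0.000338, adjusted p = 0.644 with an estimated correlation). The RNA sensor gene Ifih1 rose from 1.63 ± 0.238 FPKM (SD, n = 3) to 4.46 ± 0.669 (SD, n = 4), the 1 member past the threshold over all genes, and 3 passed adjusted over the list alone. In the same libraries the monocyte, macrophage and dendritic score was 4.56 to 4.93 in cKO against 2.70 to 3.55 in wild type, and the member Bst2 also stands in the plasmacytoid dendritic list. Ifi44 and Oas3 had log2 fold changes of 1.39 and 1.43 (limma adjusted p = 0.121 and 0.152).

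Genes of follicular B cells, B cell receptor signalling, MHC class II presentation and the ribosome fell as lists, although 0 members of these 4 lists passed limma's threshold over all genes or adjusted over the list alone. In the same libraries 86 of the 90 markers of other cell types had a positive fold change, and the monocyte, macrophage and dendritic score was 4.56 to 4.93 in cKO against 2.70 to 3.55 in wild type. At an unadjusted p under 0.05 stood 2 follicular, 3 receptor signalling, 1 MHC class II and 6 ribosomal genes. Of 26 receptor signalling genes 23 had a negative fold change, with a median of -0.34 (limma camera adjusted p = 0.000299, adjusted p = 0.766 with an estimated correlation). Blk, a kinase of the receptor pathway, stood at 108.8 ± 4.79 FPKM in wild type (SD, n = 3) and 58.9 ± 13.6 in cKO (SD, n = 4), and Cd79b, a signalling chain of the receptor, at 1092 ± 45.5 and 653 ± 81.6. The follicular list had a median of -0.30 over 9 members (limma camera adjusted p = 0.00893, adjusted p = 0.644 with an estimated correlation), with Fcer2a, the low-affinity IgE receptor CD23, at -1.04. The MHC class II list had a median of -0.59 over 13 members (limma camera adjusted p = 0.000437, adjusted p = 0.644 with an estimated correlation), with H2-Ob at -0.87. Ribosomal protein genes had a median of -0.35 with 68 of 72 negative (limma camera adjusted p = 9.62e-10, adjusted p = 0.501 with an estimated correlation), and Rps27 was the member with the smallest p, at -0.79. Quantile normalization ended the calls of the follicular, receptor signalling and MHC class II lists (limma camera adjusted p = 0.144, 0.0567 and 0.240), with medians that went from -0.30 to -0.29, from -0.34 to -0.33 and from -0.59 to -0.37.

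The B-1 cell list rose, with a median of 0.63 and all 8 members positive (limma camera adjusted p = 0.00319, adjusted p = 0.501 with an estimated correlation), and 2 members, Spn and Itgam, passed adjusted over the list alone. Itgam and Cd5 also stand in the lists of other cell types, of which 86 of 90 markers had a positive fold change in the same libraries. In lane 7 alone the B-1 median was 0.15 (limma camera adjusted p = 0.0606). The 16 remaining lists, beside the plasmacytoid dendritic one, did not pass. Fkbp11 was the 1 member of the plasma cell list that fell (median -0.25, limma camera adjusted p = 0.225). The lists of surface activation, immature and precursor B cells, immediate early and heat shock, germinal centre, marginal zone and toll-like receptor genes had medians of 0.50, 0.50, 0.25, 0.21, 0.11 and 0.13, and oxidative phosphorylation 0.01. The forkhead, unfolded protein, migration, BCL2, NF-kB, cytokine, B cell transcription factor and FOXO target lists had medians of -0.06, -0.04, -0.09, -0.11, -0.16, -0.23, -0.25 and -0.25. The median and the mean of the BCL2 family and of the forkhead and unfolded protein lists differed in sign.

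**Figure D4:**
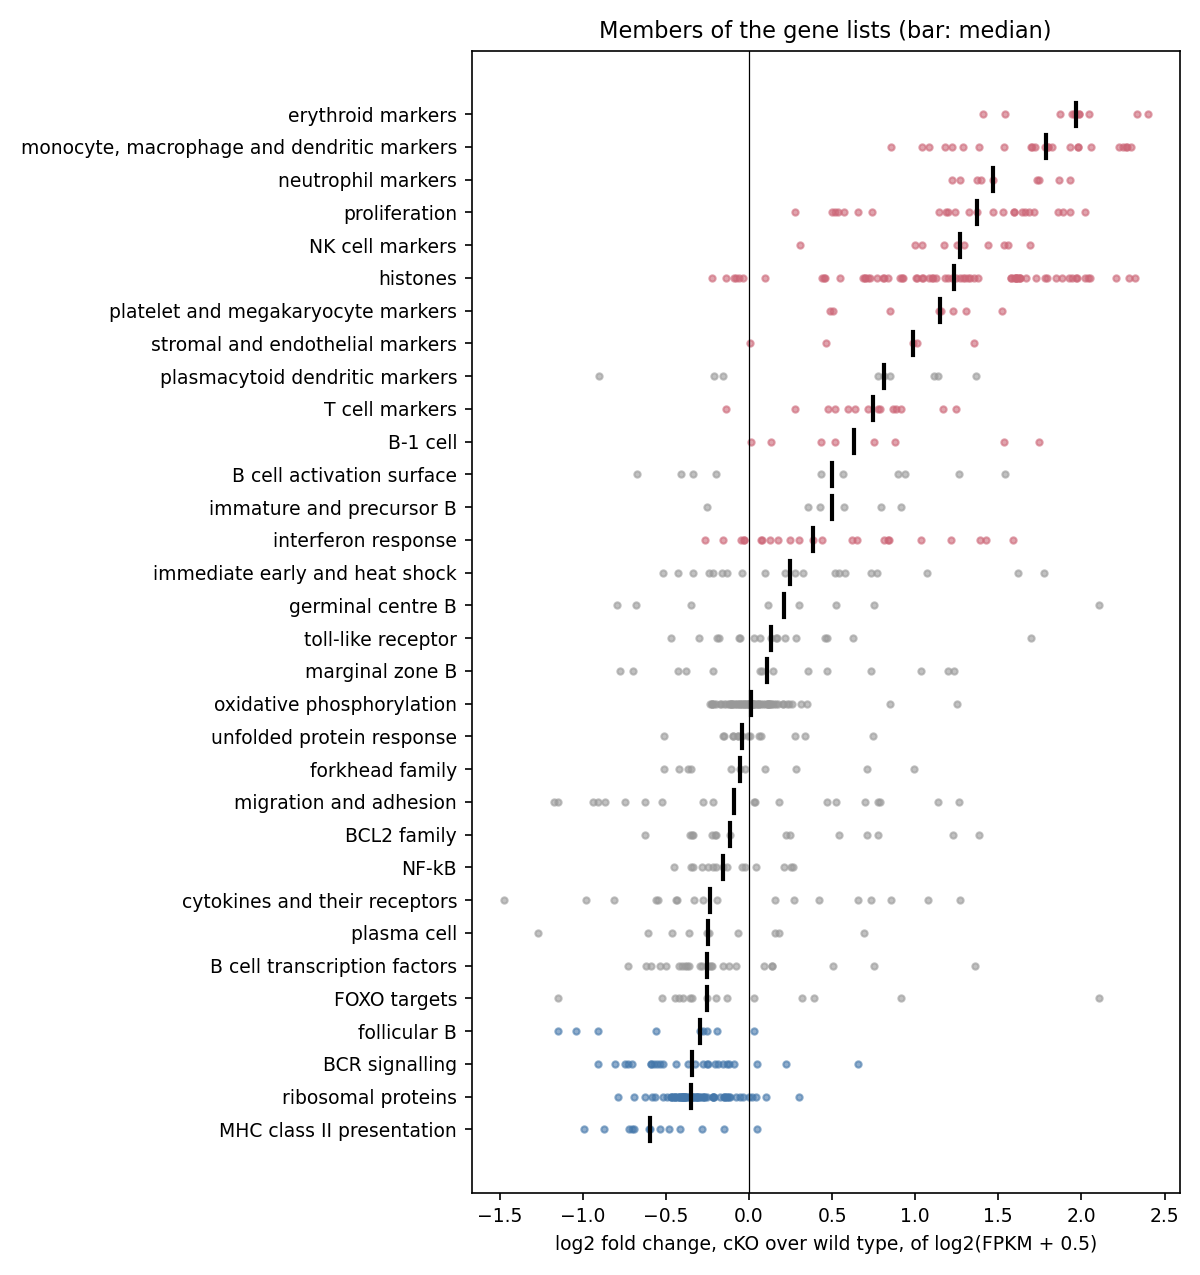
Log2 fold change of cKO over wild type on the x axis for each tested member of 32 gene lists on the y axis, with a black bar at the median. Red lists rose and blue lists fell by limma's camera with a preset correlation, and grey lists did not pass. The erythroid list has the highest median, 1.96, and the MHC class II list the lowest, -0.59.

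The authors' deposited table compares arms q1 and q2 of these libraries, so it is not independent evidence. Qpct, Lipc and the other genes called higher in cKO here were mostly higher in q2 there: of 10028 genes in both, the authors' deposited table has 1175 higher and 111 lower in q2 at q under 0.05, which took in 124 of the 128 higher and 5 of the 5 lower genes, with 0 in the opposite direction. Chance would give 15 shared higher genes (Fisher's exact test, two-sided, p = 5.99e-112). The same libraries lie under both sets, so a large overlap was likely in advance and this p adds no support. The authors' deposited table gives q = 0.0689 for Foxp1, with a negative test statistic.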

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

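The tests on marker lists, on the 5 leading genes and on the erythroid score were chosen after the values per library had been seen, and the counts over other splits of the libraries were planned before those counts were seen. The count with the lane term was first planned over all splits but the split by lane, and was limited to splits within lanes after its values had been seen.

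Among 139 values checked over the 4 cKO libraries, 5 had 1 library far from the other 3, and chance gives about 1 in 20. The 139 count a gene again for each rule that named it, while the 5 are counted once each, so their share is understated. Fpr1 was 9.10 FPKM in cKO 3 and 5.13 to 5.41 in the others, a gap of 0.928 of the range. Tubb1 was 47.5 in cKO 3 and 15.2 to 19.4 in the others (0.868). In cKO 4, Scn4a was 1.12 against 0.680 to 0.740 (0.864), Cd79b 775.4 against 611.4 to 613.2 (0.989) and Ifi44 16.1 against 6.53 to 7.52 (0.897).

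Chance could not be excluded for the 133 genes: 3 of the 35 splits of the 7 libraries into 4 and 3 gave as many, the real one included. The highest other split, 5863 genes, is the split by lane, and 2688 genes came from wild type 2, wild type 3 and cKO 4 against the rest, so structure of the libraries other than genotype calls many more genes. With the lane as a term the real split gave 1085 genes and the highest other split 484, but that split changes how many libraries of each group stand in each lane. Of the 18 splits that keep these numbers, the real one alone reached its count, 1 of 18, and the highest other gave 345, but 18 splits are too few for a share under 0.05. For the 15 gene lists chance could not be excluded, since 7 of 35 splits gave as many and the highest other split gave 18.

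Markers of other cell types were higher in the cKO libraries, in which the follicular, receptor signalling and MHC class II lists fell, and a lower share of B cells that raised every other type alike is a candidate explanation of both. Of the 28 pairs of marker lists, 3 differed by an amount that separated the genotypes, where chance gives 1.60, and 6 of 35 splits gave as many. This decides nothing with 7 libraries, so a general loss of B cell share, more cells of certain types and weaker CD43 depletion cannot be told apart from a change of the rising or falling genes in B cells themselves. CD43 depletion is directed at T cells and myeloid cells, and Spn, its target's gene, was at 19.6 FPKM in cKO and 4.83 in wild type. How far it removes erythroid, stromal or endothelial cells was not tested. The genotype itself may change the makeup of the spleen, which was not tested.

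Qpct, Lipc, Plb1, Neil1 and Slpi rose by more than the median of any marker list, and a larger share of carried-over monocytes and macrophages could be a source. Scaled by the level of the monocyte, macrophage and dendritic list from the cKO libraries of the same lane, such cells would bring 1.26 to 2.65 FPKM of Qpct and 0.716 to 1.37 of Plb1 into the wild type libraries, which held 0.106 to 0.232 and 0.00581 to 0.0273. Over the 5 genes the log2 ratio of needed to observed FPKM (0.5 added to each) averaged 1.13, 1.40 and 1.78 in wild type 1 to 3 (SE 0.16, 0.26 and 0.17), against an SD of 0.23, 0.25 and 0.50 over the 24 markers, and each of the 5 lay above each marker. The 5 genes were picked for the largest rises, and the markers set the scaling. Ratios above those of the markers therefore followed largely from the choice. These values cannot decide whether a larger share of such cells was the whole source of the rise. An earlier test, replaced after its values were seen, took the log2 excess of lane 5 within the cKO libraries. The myeloid score was higher by 0.085, NK by 1.25, T cell by 1.66 and receptor signalling by 0.83. The 5 genes averaged 1.24 above the myeloid score and 0.079 above the NK score (SD 0.49 over genes). The median gene was higher by 0.57, and this test could not tell the sources apart. Expression in B cells, a change within the myeloid cells, NK, T or other listed cells or a cell type outside the lists stays open. None of these sources was tested further.

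Proliferation and histone genes rose as lists, and erythroid precursors in the preparations may carry them. The erythroid score went with the proliferation score over the 7 libraries (Pearson r = 0.971, exact permutation p = 0.000992, and Spearman rho = 0.929, exact permutation p = 0.00675, both the same after adjustment over 2 relations) and with the histone score (r = 0.981, exact permutation p = 0.000198, the smallest possible, adjusted 0.000397, and rho = 1.00, exact permutation p = 0.000397, adjusted 0.000794). Without wild type 3 and cKO 4 r was 0.966 and 0.965, and within lanes 5 and 7 it was 0.972 and 0.991 for proliferation. With the erythroid score as a covariate the difference in proliferation score between genotypes went from 1.27 (SE 0.64) to 0.42 (SE 0.17), above 2 SE but below the bound set for excluding erythroid cells, and that in histone score from 1.19 to 0.13. The proliferation and histone differences therefore cannot be told apart from erythroid content over 7 libraries, and division of B cells stays open and was not tested.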

How the results depend on the processing

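Settings named here as added were chosen after seeing the data: LOWDATA rows kept, small RNA genes left out, each scaling together with the lane term, and the lane term without each library. All main calls that were tested kept their direction under each of the 25 alternatives, and no named gene or list that was called reversed. The groups of all 133 genes did not overlap, so hardly any setting but scaling could have turned a direction. The kept directions are therefore no sign that the calls are robust. The 133 genes changed (128 higher, 5 lower) became 107 (1 lower) with a pseudocount of 0.1, 55 (54 and 1) with 1, 0 with no filter (2237 genes at an unadjusted p under 0.05 in limma) and 6 (6 and 0) at a mean FPKM of at least 5, 3 lower without the eBayes trend, 304 (233 and 71) with median centring, 29 lower with quantile normalization, 1085 (965 and 120) with the lane term, 612 (587 and 25) in lane 5 alone, 283 (247 and 36) in lane 7 alone, whose 1 wild type library was assumed to vary like the cKO libraries, and 224 (217) at an adjusted p under 0.10. Added: 1982 (814 and 1168) with quantile normalization and the lane term, and 2228 (952 and 1276) with centring and the lane term. Leaving out 1 library gave 0 to 220 genes, 0 to 216 higher and 0 to 4 lower, and with the lane term (added) 653 to 1417 higher and 41 to 583 lower. Fewer libraries are part of each such change; otherwise the cause was not tested.

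Foxp1, short of the threshold in the main setting, passed with median centring (-0.81), quantile normalization (-0.80) and the lane term (-0.75), and when added with quantile normalization and lane (-0.80) and centring and lane (-0.84). Of 15 gene lists, 0 passed with an estimated correlation (smallest limma camera adjusted p = 0.105) and 2 with fry, the myeloid and neutrophil lists. At a mean FPKM of at least 5, 12 of the 24 lists tested passed. The remaining alternatives gave 15 to 18 of 32, with 18 under median centring and at the looser threshold of 0.10. The replicate block gave 0 genes changed, 0 higher and 0 lower in limma (1154 at an unadjusted p under 0.05), but same-numbered libraries did not deviate together (correlations of -0.41, -0.50 and -0.69), so the numbers do not pair the libraries. Depth per gene is unknown in FPKM, which limits what can be said of low genes such as Plb1.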

Other observations

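Some surface and B cell genes outside the named set, chosen after their values were seen, had groups that did not overlap, without passing the threshold over all genes. Over all genes tested 10.1% had such groups, against 5.71% by chance. The costimulatory genes Cd86 and Cd80 had log2 fold changes of 0.94 and 0.90 (limma adjusted p = 0.105 and 0.121), and 0.92 and 0.92 with the lane term (limma adjusted p = 0.00828 and 0.00539). Cd44, an adhesion receptor of activated lymphocytes, stood at 8.95 ± 0.996 FPKM in wild type (SD, n = 3) and 23.3 ± 9.37 in cKO (SD, n = 4). Cd86, Cd80 and Cd44 stand in the surface activation list, which did not pass (limma camera adjusted p = 0.0825). Of its 10 tested members 6 had a positive fold change and 4 a negative one, among them Cd40 at -0.67 and Cd69 at -0.20. Marcks, a member of the marginal zone list, stood at 22.9 ± 4.33 and 48.1 ± 12.7 FPKM, while Mzb1 of the same list stood at 124.1 ± 12.3 and 77.0 ± 13.4. Id2, an inhibitor of basic helix-loop-helix factors, had a log2 fold change of 1.36 (limma adjusted p = 0.103), and 1.24 with the lane term (limma adjusted p = 0.0015). It stands in the B cell transcription factor list, of which 19 of 25 members had a negative fold change. Several of these genes are also expressed by myeloid or NK cells, whose markers were higher in the same libraries.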
